A study of Arabidopsis thaliana with 6 samples.

How the data were processed

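The series holds 6 arrays in 6 groups, 1 array per group: roots and rosette leaves of Arabidopsis thaliana accession Col-4 grown in hydroponic culture with no added lead, with 25 ppm or with 50 ppm lead, given as lead nitrate in 2 additions to the nutrient solution. Per the labels' protocols, plants were harvested at growth stage 6 after growth at 22 °C by day and 18 °C by night, with 10 h of light, 14 h of dark and 70% humidity. Total RNA was turned into biotin-labelled cRNA and hybridised to an Affymetrix Arabidopsis array with 8297 probe sets, per the labels. The labels do not say how many plants went into an RNA sample.

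The deposited values are linear signals, 1 per probe set and array, never below 0. Their trimmed means lay near 100 on every array (2% trimmed from each end), which is how the authors' values appear to have been scaled; the software that made them is not given in the sources used here. All 6 value columns of the table were used and 0 were left out. The 50 control probe sets were set aside, which left 8247. The signals were scaled to a common 2% trimmed mean, values under the 30th percentile of all signals (8) were raised to it, and log2 was taken. The 5395 probe sets that reached the median of all signals (25.3) on at least 1 array were tested. A change measured from a value under 8 is therefore a lower bound. The number of arrays limits the precision.

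Probe sets were named from the platform's annotation, with symbols updated through gene identifiers in a RefSeq gene table of assembly TAIR10.1. That gave exactly 1 gene for 3784 probe sets (3592 loci), 70 named several genes and 4383 are unnamed here; 10 more named a gene that had no match in the RefSeq table. Of the tested probe sets, 2305 named 1 gene, covering 2186 loci. Naming favoured genes without a symbol: the locus was the only symbol for 83.4% of the named loci, against 70.5% of all genes of the RefSeq table. Of the 499 loci in the gene lists, 41 had a named probe set and 37 were tested. Over the whole RefSeq table, 3592 of 38312 genes had one. Whether the way of naming lowered the coverage of the lists was not tested. Of the 26 lists, 5 had at least 3 tested genes, 11 had 1 or 2, 8 had no named probe set and the other 2 had none that was tested.

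The design, the lists and the rule for naming genes were fixed before the data were examined. Lead was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg, threshold 0.05) on the 4 combinations of organ and lead, with 25 and 50 ppm together as lead. Its 2 residual degrees of freedom are the differences between the 25 and 50 ppm arrays, so a true dose effect counts as error, and the p-values measure only the spread between these arrays. Root was compared with leaf in limma with dose as a further term. As no group had a replicate array, changes were also counted by a rule of size without a test: at least 2-fold from the control array in the same direction at both doses. That count was set beside the same count with the 25 or the 50 ppm array in the control's place. The 25 and 50 ppm changes share 1 control array, so their correlation was set beside 100 simulations of unchanged arrays.

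For each list with at least 3 tested genes, the median log2 change was placed among 10000 random lists of named genes, matched in 10 bins of mean signal; probe sets of a gene were averaged. A list stood apart under the 2.5th or above the 97.5th percentile with both doses on the same side of 0. Genes named in the text are, per organ, up to 12 probe sets each way with the largest smaller change of the 2 doses, the 5 largest differences each way between 50 and 25 ppm, the 5 smallest p of the organ difference and of the common response, the 10 largest each way between root and leaf, and up to 4 members of each list. The text gives a selection of these.

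The code was tested on simulated data for the 5395 tested probe sets, with 200 changed. For lead in roots, 4% of probe sets changed by 1 on the log2 scale were called, 48% at 2, 94% at 3 and 98% at 4. For root against leaf, 14% were called at 1 and 88% at 2. The simulation gave probe sets of like mean signal the same normal spread, so these shares need not hold for the measured arrays. In the measured roots the gene OSM34 had a log2 change of 3.19 and did not pass. Random lists of 8 genes stood apart in 6.5% of 200 draws without a shift and in 99.5% with a shift of 1. Most lists scored below had fewer tested genes, such as 3 for sulfate and 4 for abscisic acid. The draws also left out the rule on both doses, so these shares do not describe such small lists.

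Alternatives were other scalings, floors and filters, an offset in place of the floor, leaving out each array, other fits, 1.5-fold and 3-fold rules and the list mean. A filter on a mean signal of at least 100 and the 1.5-fold and 3-fold rules between doses were added after the data were seen, as were 40 gene families. Of these, 38 were searched by words in gene names and 2 were given by locus from general knowledge.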

Results

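Gene expression was measured in roots and rosette leaves of Arabidopsis thaliana, the thale cress, after hydroponic growth without added lead or with 25 or 50 ppm lead in the nutrient solution. The series asks which genes take part in the plant's uptake of lead, its tolerance and its defence. Each combination of organ and dose was measured on 1 array, so no value below has a replicate. Median signals ran from 22.3 in the control leaf array to 29.3 in the 50 ppm root array. The average background was 192.65 on the 50 ppm root array and between 69.03 and 97.8 on the other 5. Rank correlations across all probe sets were 0.961 between the control and 25 ppm root arrays, 0.936 between control and 50 ppm roots and 0.943 between the lead-treated root arrays. In leaves they were 0.965 and 0.962 with the control, and 0.960 between the arrays of the lead-treated plants.

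The first question was what lead did in roots. The probe set with the highest smaller change of the doses has no gene name here and was 30.3-fold higher at 25 ppm and 50.1-fold higher at 50 ppm. Among named genes that were higher at both doses, AT4G33560 measured 9.21 in control roots, 172 at 25 ppm and 60.1 at 50 ppm. OSM34, an osmotin of the PR-5 type, had a signal of 189 in control roots, 1232 at 25 ppm and 2422 at 50 ppm. The class V chitinase ChiC lay under the floor in control roots and was at least 4.91-fold higher at 25 ppm and 31.8-fold higher at 50 ppm. The chitinase gene CHI (AT2G43570) measured 55.5, 216 and 471 in dose order. AT2G38870, of the PR-6 proteinase inhibitor family, measured 101, 665 and 418. AT2G42690 was represented by a pair of probe sets, which were 5.47-fold and 4.17-fold higher at 25 ppm and 12.3-fold and 9.44-fold higher at 50 ppm. CYTC-2, a cytochrome c, was 3.77-fold and 3.49-fold higher at 25 and 50 ppm, and AT4G25160 5.24-fold and 5.20-fold. Lower transcripts included UGT72E1, a glucosyltransferase acting on lignin precursors, with 401 in control roots, 57.1 at 25 ppm and 127 at 50 ppm. AT2G05530 measured 268, 22.0 and 57.3, AT4G33120 measured 315, 62.5 and 42.2, and AT3G52060 measured 506, 170 and 158. ATPMEPCRD, a pectin methylesterase, was 3.33-fold and 2.60-fold lower.

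**Figure D1:**
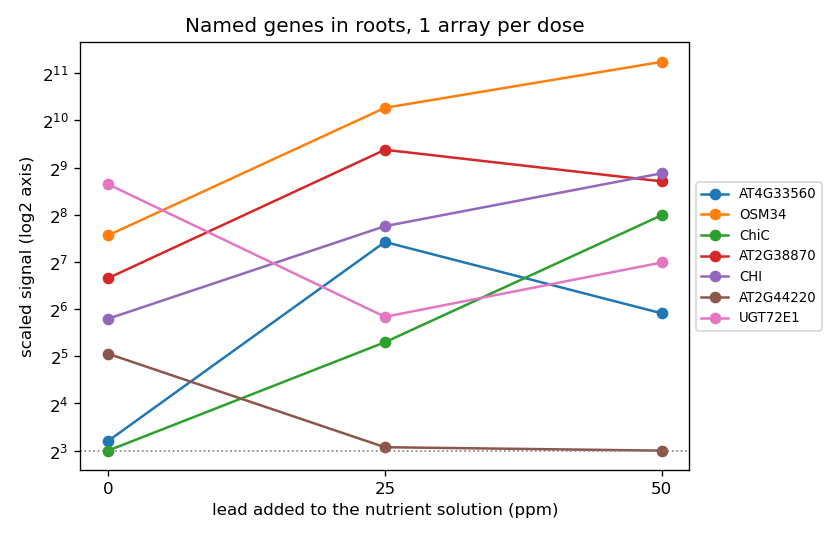
Scaled signal on a log2 axis against the lead dose in ppm for 7 named genes in roots, with 1 array at each point and the floor of 8 as a dotted line. OSM34 went from 189 to 2422, while UGT72E1 was below its control signal of 401 at both doses.

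By the rule of size, 254 probe sets were at least 2-fold different from control roots in the same direction at both doses, 156 higher and 98 lower. With the 25 ppm array in the control's place the count was 169, and with the 50 ppm array 437. In limma 0 of 5395 probe sets passed, with a lowest adjusted p of 0.217 and 332 at an unadjusted p under 0.05 where 270 would be expected by chance. OSM34 had a mean log2 change of 3.19 with a standard error of 0.48 (adjusted p = 0.650). Without the 25 ppm root array 162 passed in limma; the lone root array with lead is then assumed to vary like the leaf arrays. Without a filter 36 passed. The 2-fold count was 112 among the 2209 of 5395 probe sets with a mean signal of at least 100. It was 875 without the 25 ppm array and 542 without the 50 ppm array, whose background was high. The share that was higher was 67.4% and 45.6% in these, against 61.4% with all arrays.

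The same question in leaves gave fewer differences by the rule of size. Among transcripts that were lower with lead, Hsp70-2, a chaperone, had a signal of 321 in control leaves, 8.43 at 25 ppm and 24.1 at 50 ppm, and its other probe set was at least 8.01-fold lower at both. ZAT7, a zinc-finger stress regulator, measured 78.7, 10.1 and 10.7 on one probe set and 39.6, under 8 and under 8 on the other. WRKY53, a regulator of senescence and defence, measured 175, 58.6 and 39.4. CCS, the chaperone that brings copper to superoxide dismutase, had a signal of 468 in control leaves and was 4.84-fold lower at 25 ppm and 4.67-fold lower at 50 ppm. The pectin methylesterase ATPMEPCRB measured 157, 48.5 and 18.9 on one probe set and 114, 42.3 and 15.1 on the other. The peroxidase genes AT5G64120 and AT5G39580 were at least 4.68-fold and 2.90-fold lower. Among transcripts that were higher, HIS1-3, a drought-inducible linker histone, measured 13.5, 45.5 and 145.0. SAG29, a sugar transporter of senescing leaves, was at least 4.68-fold and 3.11-fold higher. TBL45 measured 163, 403 and 462, AT5G61520 measured 62.8, 147 and 150.3, and AT4G14020 measured 27.0, 71.7 and 89.1.

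**Figure D2:**
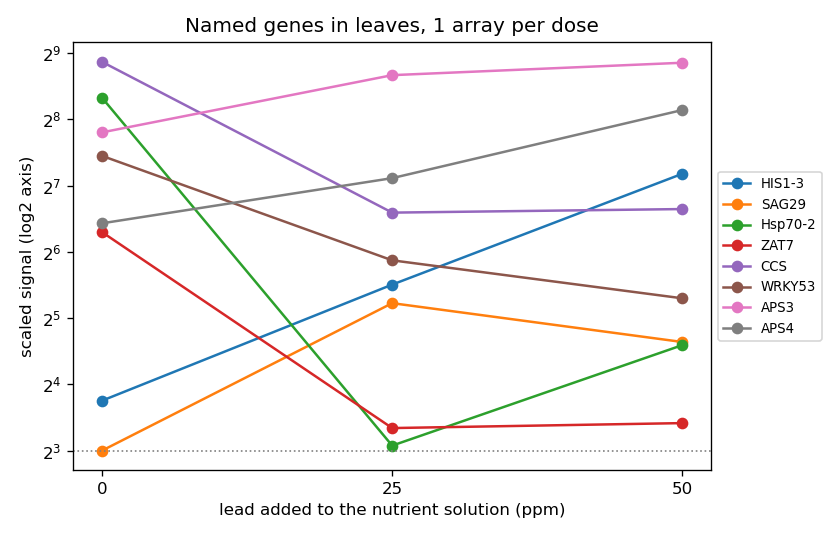
Scaled signal on a log2 axis against the lead dose in ppm for 8 named genes in leaves, with 1 array at each point and the floor of 8 as a dotted line. CCS lay at 468 in the control and was 4.84-fold and 4.67-fold lower with lead, while APS3 and APS4 were higher at both doses.

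By the rule of size, 109 probe sets in leaves differed, 53 higher and 56 lower. The control array was no more distinct than the others, as the count was 115 with the 25 ppm array and 194 with the 50 ppm array in its place. In limma 0 passed, with 134 at an unadjusted p under 0.05 where 270 would be expected by chance and a lowest adjusted p of 1. CCS had a mean log2 change of -2.25 with a standard error of 0.33. Without a filter 22 passed in limma, 3 of them higher, with the same limit from values tied at the floor as in roots. The 2-fold count was 438 without the 25 ppm array, 315 without the 50 ppm array and 32 among the 2209 probe sets with a mean signal of at least 100. With a floor at the 10th percentile it was 203, of which 118 were higher. With a floor at the 50th percentile 23 of 67 were higher, and by a 3-fold rule 7 of 27.

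**Figure D3:**
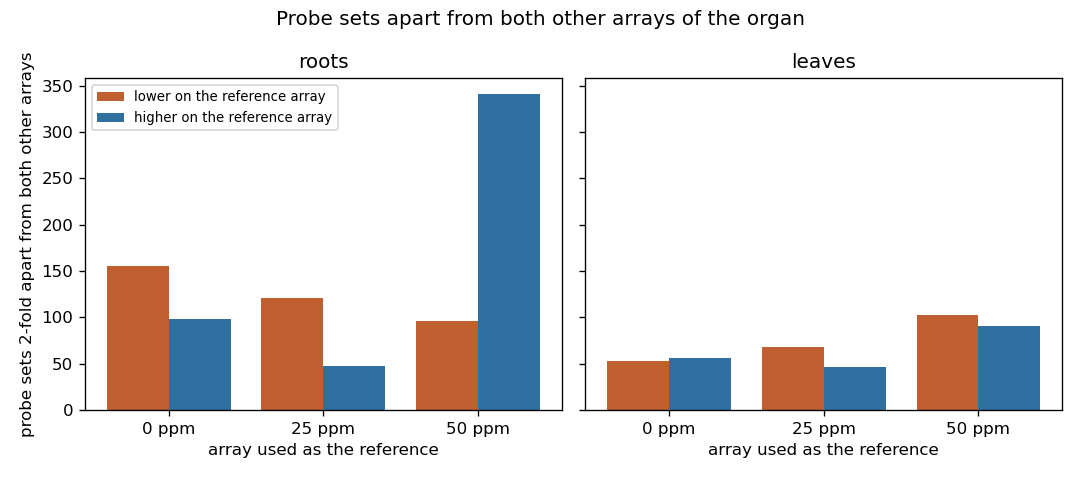
Number of probe sets at least 2-fold apart from both other arrays of the organ, with each array in turn as the reference; bars show those lower and higher on the reference array. The 50 ppm root array had 341 that were higher, and the control leaf array 53 lower and 56 higher.

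The changes at 25 and 50 ppm shared a control array. Across probe sets, which are not independent replicates, they correlated at 0.491 in roots and 0.472 in leaves, where simulated unchanged arrays gave 0.501 and 0.499. The covariance was 0.281 in roots against 0.323 simulated, and 0.156 in leaves against 0.179. The simulated spread was taken from the differences between the 25 and 50 ppm arrays, so a true dose effect counted as noise there. Neither covariance was above the simulated one. For that reason the comparison cannot show whether a response shared by both doses was present or absent.

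Between the doses, 764 probe sets in roots were at least 2-fold apart, 563 higher and 201 lower at 50 ppm. AT4G11190 measured 47.5 in control roots, 21.2 at 25 ppm and 699 at 50 ppm, AT2G25510 measured 115, under 8 and 160, and the chitinase family gene AT4G19750 measured 36.8, 9.61 and 183. GLR2.3, a glutamate receptor-like gene, measured 282, 407 and 17.0, AT5G26130 measured 325, 540 and under 8, and the light-harvesting gene LHB1B2 measured 87.7, 87.1 and 11.6 on one probe set, while the other, near the floor, measured 8.71, 9.91 and 9.29. In leaves 427 probe sets were 2-fold apart, 216 higher and 211 lower at 50 ppm. AT1G76960 measured 489, 312 and 1615, AT1G54010 measured 67.0, 14.9 and 89.4, and AT4G16260 measured 12.8, under 8 and 91.4. AT2G38870 measured 237, 257 and 45.7, and AT3G47380 measured 236, 199 and 32.6 on one of its probe sets. These differences had no test. With quantile normalization 60% of the root differences were higher at 50 ppm, against 73.7%.

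Whether roots and leaves responded alike was tested directly. Lead changes in roots and leaves had a Pearson correlation of 0.0294 and a Spearman correlation of 0.0404 across 5395 probe sets. No simulated value was set beside these. Probe sets under the floor on all 3 arrays of an organ have a change of 0 there, so values near 0 do not show that the organs responded unlike. For the difference between organs 0 passed in limma, with a lowest adjusted p of 0.676 and 202 at an unadjusted p under 0.05. The smallest p of named genes included Hsp70-2, whose log2 change in roots exceeded that in leaves by 5.77 on 1 of its probe sets, and AT4G13180, by 2.77. OSM34 was also among them, but lay under the floor on all 3 leaf arrays, so that its 3.19 is the root change and its leaf change was not measured. For a response common to both organs 0 passed, with 244 at an unadjusted p under 0.05. CCS had a common log2 change of -1.51, with root signals of 300.5, 203 and 151 in dose order, and AT4G14020 had 1.39. Without the 25 ppm root array 104 passed for the difference and 100 for the common response, and without a filter 58 and 56.

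Of the 5 gene lists with at least 3 tested genes, sulfate uptake and assimilation stood apart in both organs. Its tested members were APS3 and APS4, which encode ATP sulfurylases, and SIR, sulfite reductase. In leaves all 3 were higher at both doses: APS4 measured 86.3, 138 and 282, APS3 measured 224, 407 and 463, and SIR measured 156, 191 and 237. The list's median log2 change there was 0.96, at percentile 99.9 of matched random lists. In roots APS4 measured 366, 827 and 932, APS3 measured 76.3, 102 and 213, and SIR 268, 218.0 and 382, with a median of 0.95 at percentile 99.2. In roots the median was 0.42 without the 50 ppm array, and the list no longer stood apart. In limma 0 of its members passed in either organ, over all probe sets or adjusted over the list alone.

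The other 4 of these 5 lists did not stand apart in either organ, although 2 of them did under some alternatives, and in limma 0 of their probe sets passed for lead, over all probe sets or adjusted over the list alone. Photosynthesis genes had a median log2 change of 0.25 in leaves (percentile 96.1), with 0.48 at 25 ppm and 0.05 at 50 ppm. This list lay near the threshold, and it stood apart in leaves without the control root array (percentile 97.8), without the 25 ppm root array (98.3) or without the 50 ppm root array (98.2), each of which left its median at 0.25, and without the 50 ppm leaf array (99.7). Without the 25 ppm leaf array it lay at percentile 48.4, and with quantile normalization its median was 0.02 at percentile 57.5. The abscisic acid, drought and cold list had a median of 0.27 in leaves and -0.25 in roots. Its direction in roots turned with the processing: the median was 0.80 with the floor at the 10th percentile, where the list stood apart as higher (percentile 99.7), 0.14 with an offset in place of the floor, 0.13 with the mean in place of the median and 0.06 without the 25 ppm array. In leaves it was 0.87 and stood apart without the 50 ppm array, and it was -0.06 without the 25 ppm array. In roots its cold-inducible member KIN2 measured 104, 261 and 1111 on one probe set and 150.5, 350.1 and 1014 on the other, while COR47, a dehydrin, measured 1322, 885 and 306 on one and 1785, 1298 and 674 on the other. In leaves antioxidant enzymes had a median of -0.16 and glutathione transferases of 0.07. In roots both medians were 0, set by TAPX and GSTU18, which lay under the floor on all 3 root arrays; of the other members 2CPA had a log2 change of -0.57 and SAPX of 0.92, GSTF3 of -0.27 and GSTU16 of 0.17. In leaves the antioxidant median was above 0 without the 25 ppm array (0.12), without the 50 ppm array (0.09) or as a mean (0.01), and that of glutathione transferases was -0.19 without the 50 ppm array. Among lists with 1 or 2 tested genes, the metal transporter ZIP9 measured 27.5, 76.6 and 71.6 in roots, the expansin EXPA4 measured 123, 353 and 409, and glutathione reductase GR1 measured 133, 254 and 251. GR1 in leaves measured 201, 147 and 130.1. Adjusted over the list alone, 1 member passed in limma in each of 4 of these small lists: ZIP9 among metal transporters and EXPA4 among cell wall genes in roots, WRKY53 among defence genes and SAG29, the 1 tested senescence gene, in leaves. Over all probe sets 0 of them passed.

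The organs differed far more than the lead groups did. In limma 1674 probe sets were higher in roots and 1168 higher in leaves. Peroxidase genes were prominent in roots: AT3G32980 was at least 319-fold higher than in leaves (log2 difference 8.32, standard error 0.22, adjusted p = 1.2e-05), AT5G64100 at least 312-fold and AT4G30170 at least 184-fold, higher in 3 of 3 root arrays. AT3G32980 lay at or under the floor on all 3 leaf arrays, which therefore added no spread to its standard error or p-value. The beta-glucosidase BGLU21 was at least 303-fold higher. Leaves had more of the photosystem genes PSBW, at least 631-fold on one of its probe sets, and PSAE1, at least 450-fold on one of its probe sets, and of RCA, Rubisco activase, at 229-fold. All 8 tested photosynthesis genes were higher in leaves. The median difference over all tested probe sets was 0.30 in favour of roots, and 0.14 when arrays were scaled to the median of well measured probe sets.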

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

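The tests of RNA degradation, of green leaf RNA, of weak-signal noise in leaves and of the spread between single arrays were chosen after the results were seen, as was the signal minimum of 100, and the intervals set beside the tests were added after their values were seen.

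Hsp70-2, AT2G18690 and AT2G32210 were picked out as at least 2-fold higher in roots and at least 2-fold lower in leaves at both doses. Hsp70-2 met this rule on 1 of its probe sets and not on the other. For these genes, in that order, the root change exceeded the leaf change by 5.77 (on that probe set), 3.69 and 4.58 on the log2 scale. In limma 0 probe sets passed for that difference, with 202 at an unadjusted p under 0.05. In all, 6 probe sets were higher in roots and lower in leaves, where independent lists would share 1.62, and 6 were higher in both organs, where 1.53 would be shared. Another 3 were lower in roots and higher in leaves against 0.963, and 0 were lower in both against 1.02. These expected numbers take every probe set as equally likely to change 2-fold, which was not checked. A larger overlap therefore does not show a response linked between the organs. The spike-in controls, which no comparison used, had a median signal on the 25 ppm leaf array of 1.71 times that on the control leaf array.

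The 50 ppm root array stood apart from both other root arrays at 437 probe sets, 341 of them (78%) higher there, and with quantile normalization at 427, 291 of them (68.1%) higher. RNA of green leaves is argued against: 7 of 11 photosynthesis probe sets lay under the floor there, and the highest share of leaf RNA that any of the 11 allows, 1.42%, would supply the gain of 3 of the 341 (0.88%). Degraded RNA would raise the 3' to 5' ratios of control transcripts, which were 1.16 for GAPDH and 2.00 for ubiquitin against 1.28 and 2.23 on the control root array and 0.826 and 2.06 on the 25 ppm root array; the gap to the control exceeded the difference between those arrays for ubiquitin and not for GAPDH, which leaves this open. At a mean signal of at least 100, 149 probe sets stood apart, and 111 of them (74.5%) were higher at 50 ppm. The exact binomial interval was 66.7 to 81.3%, but it takes probe sets of the same array as independent, which they are not. The excess of higher values was thus not confined to weak signals. That argues against weak signals raised by the high background as its whole cause among these 149. For probe sets with a lower mean signal this cause stays open. The higher lead dose, carried by the same single array, stays open and untested.

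The 56 probe sets that were lower in leaves at both doses hold Hsp70-2, ZAT7, WRKY53 and CCS. Under 3 other scalings at least 89.3% were still 2-fold lower at both doses. The lowest share was that of quantile normalization, where the median of their smaller log2 decrease was -1.40 (bootstrap interval -1.65 to -1.22). That argues against the choice among these scalings as the whole cause. They moved the control leaf array by medians of only 0.0694 (quantile), 0.00123 (no scaling) and 0.107 (median) on the log2 scale. Shifts this small could not test a larger error of scaling. The spread between single arrays may account for the number of the 56, as 91 probe sets were lower on both others with the 50 ppm array in the control's place, though 47 with the 25 ppm array. Noise of weak signals stays open too, with a median control signal of 113 and a bootstrap interval of 76.1 to 145. An effect of lead was not told apart from these, and handling of the control plants could be judged from 1 touch gene only, ZAT10, with a log2 change of -0.86 in leaves.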

How the results depend on the processing

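The signal minimum of 100 and the 1.5-fold and 3-fold rules between doses were chosen after the data were seen; the other alternatives were set beforehand. Of the values of named genes under the alternatives, 2517 stayed the same, 8 passed the test where they had not, 7 moved and 30 reversed. For tested changes, the same means no turn of sign and the same side of the threshold. For lead, where 0 passed in the main fit, that is not passing again. For differences between doses it means a shift under the standard error of the lead change. A value of 0 could not count as reversed. The cause was not tested unless a cause is given. Root against leaf lay between 2006 and 3007 probe sets except at a mean signal of at least 100, where fewer were tested and 1356 passed. With that minimum 2209 of the 5395 probe sets were tested. Among these, 112 were 2-fold changed with lead in roots and 32 in leaves, and between doses 262 in roots and 166 in leaves. Without a filter 36 passed for lead in roots, 22 in leaves, 58 for the difference and 56 for the common response, and the sulfate medians were 0.53 in roots and 0.70 in leaves. A 1.5-fold rule gave 708 in roots and 439 in leaves with lead, and between doses 1808 and 1264; a 3-fold rule gave 76, 27, 308 and 128. A floor at the 10th percentile gave 203 changes in leaves, a median of 0.77 for glutathione transferases and of 0.80 for the abscisic acid list in roots, and -0.23 for ZIP9 in leaves. A floor at the 50th percentile gave 67 changes with lead in leaves and 251 between doses. An offset in place of the floor gave 72 in leaves, 0.14 for the abscisic acid list in roots and -0.00090 for ZIP9 in leaves. With the mean in place of the median the abscisic acid list in roots was at 0.13 and photosynthesis at -0.23. Quantile normalization gave 0.022 for photosynthesis in leaves, -0.059 for RCA in roots, and in leaves -0.074 for LHCB4.1, -0.030 for PSBW and for PSBY, -0.0043 for KIN2 and 0.032 for EXPA8. Leaving out 1 array at a time gave 0 to 162 for lead in roots, 0 to 104 for the difference and 0 to 100 for the common response, the highest each without the 25 ppm root array, which leaves a lone root array with lead. It gave 250 to 875 2-fold changes in roots and 108 to 438 in leaves, fewer arrays having to pass the rule. List medians ran from 0.42 to 1.35 for sulfate in roots and 0.68 to 1.05 in leaves, and -0.16 to 0.12 for antioxidants in leaves. They ran from 0 to 0.35 for glutathione transferases in roots and -0.19 to 0.43 in leaves. For abscisic acid they ran from -0.27 to 0.058 in roots and -0.061 to 0.87 in leaves. For photosynthesis they ran from -0.19 to 0 in roots and 0.046 to 0.48 in leaves. With each list counted once per organ, 1 to 4 results stood apart, against 2 of 10 with all arrays. The lowest was 1 of 5, without the control leaf array, where lists in leaves could not be scored. In roots, reversed genes ran from -1.15 to 0.61 (GSTF3), -0.48 to 0.25 (GR2), -0.58 to 0.39 (GI), -0.35 to 0.14 (ZIP6), -0.72 to 0.93 (RCA), -0.92 to 0.14 (PDC2), -0.88 to 0.53 (PSAE1), -2.43 to 1.74 and -0.26 to 1.49 (ZAT10) and -0.30 to 0.51 (SIR). In leaves they ran from -1.01 to 0.0018 (EXPA4), -0.30 to 0.44 (GSTF3), -0.45 to 0.13 (SAPX), -0.54 to 0.25 (TAPX), -0.35 to 0.72 and -0.20 to 0.79 (COR47), -0.14 to 0.67 (GI), -0.47 to 0.028 (THI2.1), -0.11 to 0.37 (ZIP6), -0.034 to 0.62 (PSBY), -0.61 to 0.99 (LTI30) and -0.086 to 0.068 (EXPA8). Between 26.0 and 33.6% of probe sets lay under the floor on an array. As the floor was set at the 30th percentile of all signals, shares near 30% follow from that choice and do not measure signal over background.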

Other observations

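Apart from the limma fit of root against leaf, the tests in this part were chosen after the data were seen. Of 15 tested genes found by the words for UDP-glycosyltransferases, enzymes that attach sugars to small molecules, 11 were higher in roots at both doses of lead and 1 was lower at both, and the median log2 change was 0.55. That median was 0.33 at 25 ppm and 0.77 at 50 ppm, where the array had a high background. IAGLU, which conjugates auxin, had log2 changes of 1.61 and 2.69 at 25 and 50 ppm, UGT73B1 had 1.52 and 1.51, and UGT72E1 had -2.81 and -1.66, while UGT87A2 had 0.35 at 25 ppm and 2.80 at 50 ppm. In leaves 9 of the 15 were higher at both doses and 3 were lower at both, with a median of 0.25 at percentile 95.6 of matched random lists, and at percentile 98.8 for 25 ppm alone. A difference between the organs was not tested for the family. Of 9 tested chitinase genes, 5 were higher at both doses and 0 were lower at both, with a median of 0.86, which was 0.31 at 25 ppm and 2.22 at 50 ppm. ChiC and CHI led them, with changes of 3.64 and 2.52. AT2G43590, AT4G19720, AT4G19750 and AT4G19760 were lower than control roots at 25 ppm, with log2 changes of -1.2, -0.7, -1.9 and -2.3. At 50 ppm, on the array with the high background, the same genes were higher, with 1.4, 2.5, 2.3 and 1.5. In leaves the chitinase median was -0.16, and -0.35 at 50 ppm, with AT4G19720, AT4G19750 and ChiC under the floor on all 3 leaf arrays. The medians over both doses kept their sign under the 4 scalings.

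As a hypothesis, lead may raise these families in roots. Against matched random lists the percentiles were 99.9 for chitinases and 99.96 for UDP-glycosyltransferases. At 25 ppm alone they were 94.4 and 99.1. As the families were chosen for root medians that hold the 25 ppm change, and both doses share 1 control array, these percentiles do not settle whether the 50 ppm array alone accounts for either family. These families were noticed among 40 looked at, of which 25 had at least 3 tested genes. In roots 5 of the 25 stood apart, where 1.25 would by chance; the share of 20% has an exact binomial interval of 6.83 to 40.7%, and the families overlap, so that choosing the highest among many remains a candidate explanation. In leaves 2 stood apart.

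Of 37 tested class III peroxidases, 31 were higher in roots than in leaves in limma and 1 was higher in leaves. With lead their members went both ways: in roots 13 were higher and 11 lower at both doses, and in leaves 10 were higher and 3 lower. By the rule of size, on all probe sets of the gene, 3 were higher in roots, AT4G36430, AT3G49960 and AT2G41480, and 1 was lower, AT3G01190, while in leaves AT5G64120 and AT5G39580 were lower.

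For root against leaf, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many probe sets as the real one, which is the real split itself. It gave 2842 and the highest of the others 0. Each of the others had both organs on each side, so the organ difference counted as error there and low counts follow from that. The splits are too few for a share under 0.05.

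Some unnamed probe sets differed more than the named ones. The unnamed probe set that was highest with lead in leaves measured under 8, 126 and 1350.1 there in dose order, and 127, 2142 and 1758 in roots. Another measured 629 in control roots, 18.7 at 25 ppm and 22.5 at 50 ppm.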
